A study of Homo sapiens with 6 samples.

How the data were processed

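Stranded mRNA libraries of Cal27 and Cal27-shGRK2 cells were sequenced, 3 libraries per group by their titles, which also give the replicate numbers 0, 1 and 2. Cells were grown in serum-containing medium and harvested before confluence, per the labels' protocols. Reads were processed with Bowtie2 2.2.6, TopHat2 2.1.0 and Cuffdiff 2.2.1 on hg38, per the submitters' processing notes, which do not give the role of each tool or the strand setting. The gene annotation used for counting is not given in the sources used here.

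The deposited table holds 18678 genes with FPKM (fragments scaled by transcript length and by the library's mapped fragments) per library, per the file headers. It also holds the authors' FPKM value per condition, the log2 fold change, a test statistic (a score), and p-values and q-values of the authors' comparison, per the file headers. An estimate of 0 is written as 0.0001 in the deposited FPKM columns. Because abundance was estimated by the authors' software rather than counted, genes that overlap or share sequence can exchange signal, and an exact 0 can be a failed estimate: 88 genes were at 0 in 1 library and above 3 FPKM in another. Low values did not fall on common steps of 1 read, as the fullest 0.02-wide bin of log2 ratios held 2.94% to 7.27% of low genes, so depth per library is unknown and no counting interval is given. GAPDH, ACTB, EEF1A1, KRT8 and KRT18 and the mitochondrial genes were not among the 18678 genes of the table, so they could not be analysed here. Totals per library leave them out, so the rescaling to a common total used below is not a full TPM. Gene identifiers were matched to GENCODE version 29, with 18503 of 18678 (99.1%) found, and older symbols were paired with current ones.

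Libraries were compared before averaging. Cal27-shGRK2 replicates 0 and 1 were identical in all 18678 genes, whereas other pairs within a group were identical in 55 to 94 genes. They were counted once, so the planned comparison of 6 libraries became 5, with 3 Cal27 and 2 Cal27-shGRK2. Which of the replicate numbers 0 and 1 the values belong to is unknown. The authors' condition value was compared with the mean of the columns at a relative tolerance of 1e-04, over genes with a mean condition value of at least 1 FPKM.

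Genes with a mean of at least 1 FPKM over the 5 libraries were tested on log2(FPKM + 1) with limma 3.58.1 (trend and robust empirical Bayes, R 4.3.3, 3 residual degrees of freedom per gene), two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. Folds given for single genes are ratios of mean FPKM, whereas counts of genes with at least a 2-fold change use the log2 scale. The script was tested on simulated data with the same 13377 genes and library numbers and 200 changed genes. It recovered 88.1%, 98.5% and 100% of changes of 0.5, 1 and 2 on the log2 scale, with 6.83% false calls, and called 6 genes and 0 lists when nothing was changed. Genes were simulated as independent, with the variances of the fit. The simulation therefore cannot show how correlation between genes affects the calls of lists. GRK2 was also tested with an exact permutation test.

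Gene lists were fixed before the data were examined. Of 32 lists, 29 had at least 3 tested members and were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over those lists. Of these, 12 passed, and 0 passed with a correlation estimated from the residuals, where 2 had an unadjusted p under 0.05. That form of camera also rests on the 3 residual degrees of freedom, which raises its p-values even where the correlation is small. For squamous differentiation the estimated correlation was 0.020, near the preset 0.01, yet camera's unadjusted p went from 5.9e-05 to 0.035. The lost calls therefore cannot be put down to correlation between genes alone. The genes named were fixed by rule before the data were examined. They are GRK2, and the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 5 FPKM in the higher group, no overlap between groups and no antisense, microRNA, small nucleolar or placeholder name. For each list past the threshold they include up to 4 called members with the largest change in its direction and up to 2 against it. They also include up to 4 called members per direction of the junction and mesenchymal lists, 9 chosen markers, and the other receptor kinases and arrestins. Of the genes taken by the rule, 1 is not reported here. Genes chosen after their values were seen are said to be so.

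Alternatives fixed before the data were examined were a pseudocount of 0.1, no filter beyond a value above 0, a mean of at least 5 FPKM, median-of-ratios scaling, rescaling to a common total of 1000000 (TPM), quantile normalization, limma without trend and not robust, a replicate block, leaving out each library, and the estimated correlation in camera. Alternatives added after seeing the data were a second form of the replicate block, with the shared values as replicate 1 rather than 0, all 6 columns as deposited, and an additional Cal27-shGRK2 library computed as 3 times the authors' mean minus the 2 distinct columns. Count-based tests were not run because the deposited values are not counts. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.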

Results

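Gene expression was measured by stranded mRNA sequencing in Cal27, an established human cell line from a squamous cell carcinoma of the tongue, and in Cal27-shGRK2, the same line carrying a short hairpin RNA against GRK2. GRK2 is a serine/threonine kinase that phosphorylates activated G protein-coupled receptors. The labels name 3 libraries of each group, and they say neither whether the Cal27 cells carried a control vector nor how many hairpin sequences or clones were used. The columns of Cal27-shGRK2 replicates 0 and 1 held identical values in all 18678 genes, which is less than any sampling noise, and were counted as 1 sample. Every comparison is therefore of 3 Cal27 libraries with 2 Cal27-shGRK2 libraries. The labels do not say that the libraries came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The values were FPKM, from which sequencing depth could not be recovered. The FPKM in the table summed to between 590163 and 644832 per library, and 13269 to 13369 genes reached 1 FPKM in each.

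The comparison asks what differed between Cal27-shGRK2 and Cal27 cells, in a study whose title concerns the epithelial phenotype of head and neck carcinoma. GRK2 itself (listed as ADRBK1, ENSG00000173020.10, at chromosome 11 from 67266410 to 67286556 on the plus strand in GENCODE version 29, hg38) was lower in both Cal27-shGRK2 libraries. Its FPKM was 55.3, 59.4 and 55.8 in the Cal27 libraries and 17.3 and 16.6 in the Cal27-shGRK2 libraries, a 3.35-fold lower mean. The log2 fold change was -1.69 ± 0.06 (SE, n = 3 and 2, limma adjusted p = 3.8e-11). The exact permutation test over the 10 splits of the 5 libraries gave a two-sided p = 0.1, the smallest it can give. Among other receptor kinases and the beta-arrestins, which bind phosphorylated receptors, ARRB2 fell by 0.99 and GRK6 by 0.38 on the log2 scale. ARRB1 was higher by 0.32, a call that was lost (adjusted p = 0.089) without the library shared by replicates 0 and 1. GRK3 (listed as ADRBK2) had a log2 fold change of 0.13 ± 0.10 that did not pass (limma adjusted p = 0.34). GRK5 lay under the expression filter, at 0.36 to 0.52 FPKM in the 5 libraries.

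In Cal27-shGRK2 cells several keratins and cornified-envelope genes of stratified squamous epithelium, among them KRT14, KRT13 and SPRR1A, were far lower, interferon-stimulated genes were lower, and collagen VI, fibronectin and vimentin were higher. Of 13377 genes tested, 3957 (29.6%) passed an adjusted p of 0.05 in limma, 2008 higher and 1949 lower in Cal27-shGRK2. At least a 2-fold change on the log2(FPKM + 1) scale was seen in 336 of these, 161 higher and 175 lower. The libraries of the 2 groups did not overlap in 53.3% of the genes tested, where chance gives 20%. The count of genes past the threshold was 2600 without the library shared by Cal27-shGRK2 replicates 0 and 1, where genes lower numbered 1088, and genes higher numbered 1218 without replicate 2 of that group. With each library rescaled to a common total of the genes in the table (TPM), the split was 2927 higher and 1575 lower, against 2008 and 1949 as deposited. The count with at least a 2-fold change rested on the settings, with 533 genes at a pseudocount of 0.1 and 180 with a mean of at least 5 FPKM.

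**Figure D1:**
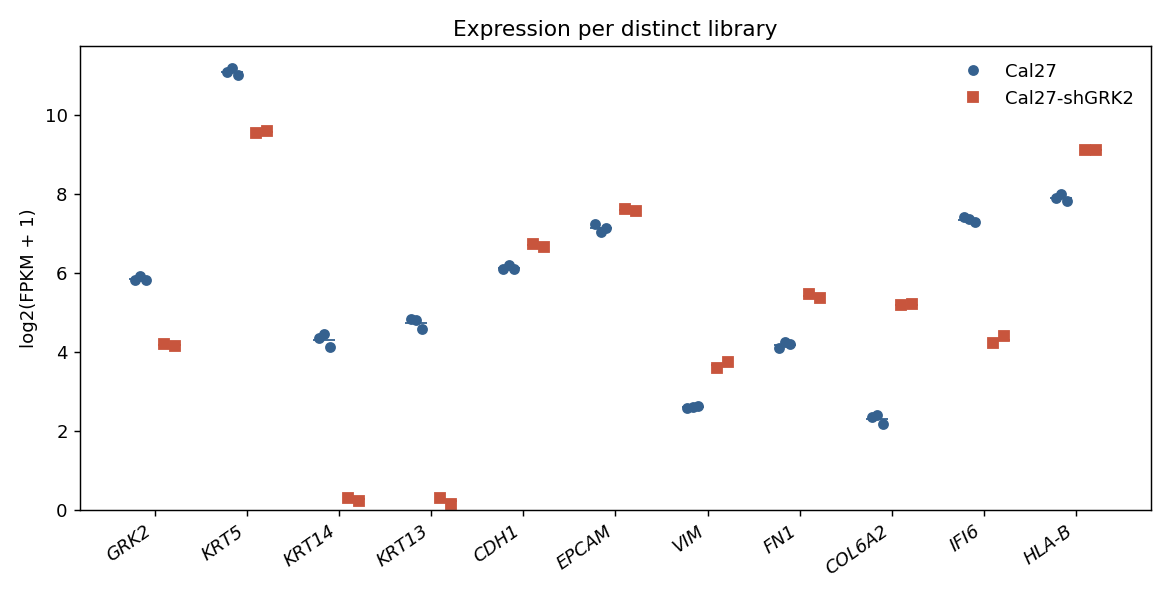
Expression of 11 genes as log2(FPKM + 1) in each distinct library, with Cal27 as circles (n = 3) and Cal27-shGRK2 as squares (n = 2) and a line at the mean of each group. KRT14 and KRT13 lay near 0 in both Cal27-shGRK2 libraries, KRT5 was lower but still abundant, and CDH1, EPCAM, VIM, FN1, COL6A2 and HLA-B were higher in both.

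Squamous identity genes were among the largest losses. All 9 tested members of the stress and hyperproliferation keratin list fell, with a median log2 fold change of -2.45. Among them were the alarmins S100A8 (-3.65 ± 0.09, SE), which went from 25.7 ± 1.47 (SD, n = 3) to 1.13 ± 0.241 FPKM (SD, n = 2), and S100A7 (-2.77). KRT17, a keratin of activated keratinocytes, fell from 446 ± 29.5 to 53.8 ± 2.14 FPKM (log2 fold change -3.03). KRT6A had a log2 fold change of -3.42 ± 0.46 (adjusted p = 0.019), but with FPKM of 6.03 and 15.4 in the 2 Cal27-shGRK2 libraries its call was lost without any of the Cal27 replicates 0, 1 or 2 (adjusted p = 0.081, 0.076 and 0.083). Reads of KRT6A can be shared with the near-identical KRT6B and KRT6C, so the split between them is uncertain. Of 22 basal keratinocyte genes, 16 fell and 4 rose, with a median of -0.66. KRT14 fell from 18.9 ± 2.23 to 0.197 ± 0.053 FPKM (log2 fold change -4.05), its partner KRT5 from 2187 ± 126 to 756 ± 23.9 FPKM (-1.53), and the transcription factor SOX2 from 6.91 ± 0.573 to 0.103 ± 0.0165 FPKM (-2.84). Against that direction, the hyaluronan receptor CD44 rose by 1.05.

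Of 26 tested squamous differentiation genes, 15 fell and 6 rose, with a median of -0.38. The mucosal keratin KRT13 had a log2 fold change of -4.51, and the cornified-envelope precursors SPRR1A, SPRR1B and SPRR3 had -4.47, -3.53 and -2.70. SPRR1A was listed at 0 in Cal27-shGRK2 replicate 2, and genes of the SPRR family can share reads, which makes their single values uncertain. The kallikrein proteases KLK5 (0.98) and KLK6 (0.96) rose. Adjusted over the list alone, the counts were 9 lower for the stress keratins, 16 lower and 4 higher for the basal genes, and 16 lower and 6 higher for squamous differentiation. The camera test with a preset correlation of 0.01 placed all 3 lists lower (adjusted p = 1.1e-11, 1.3e-07 and 2.4e-04). None of these calls held with a correlation estimated from the residuals (adjusted p = 0.39, 0.49 and 0.39 with an estimated correlation), a test that also has only 3 degrees of freedom. The squamous differentiation call was also lost when the filter was a mean of at least 5 FPKM (adjusted p = 0.072).

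The mesenchymal genes that reached the filter were higher on balance, while the epithelial junction genes moved both ways. Of 18 tested mesenchymal genes, 10 rose and 2 fell, with a median of 0.28. The collagen VI chains COL6A2 (3.93 ± 0.407 to 35.6 ± 0.229 FPKM, log2 fold change 2.89) and COL6A1 (1.68) led, followed by fibronectin, FN1 (17.2 ± 0.959 to 41.6 ± 2.49 FPKM, 1.23), and the intermediate filament vimentin, VIM (5.03 ± 0.127 to 11.7 ± 1.04 FPKM, 1.08). N-cadherin, CDH2, rose by 0.33. The actin-binding protein TAGLN fell by 1.07. The EMT factor SNAI2 had a log2 fold change of -0.27 (adjusted p = 0.018), a call that was lost without Cal27 replicate 0 (adjusted p = 0.064) and without the Cal27-shGRK2 library shared by replicates 0 and 1 (0.15) or replicate 2 (0.074). It was also lost under median-of-ratios scaling (0.050) and rescaling to a common total (0.12), and with limma without trend (0.075). ZEB1, another EMT factor, lay under the filter in all libraries, at 0.04 to 0.12 FPKM in Cal27 and 0.20 and 0.25 FPKM in Cal27-shGRK2. It was therefore not tested here, but the authors' deposited comparison marks it as significant and higher (log2 fold change 1.34, q = 0.018). The counts adjusted over the list alone were 10 higher and 3 lower. Camera placed the list higher (adjusted p = 0.0017), and adjusted p = 0.54 with an estimated correlation.

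Of 38 tested epithelial junction genes, 11 rose, 14 fell and 13 did not pass, with a median log2 fold change of -0.03 and no shift of the list (camera adjusted p = 0.54, and 0.91 with an estimated correlation). It had 13 higher and 15 lower when adjusted over the list alone. Among the members that rose, occludin, OCLN, had a log2 fold change of 0.80, claudin CLDN3 0.70, cingulin CGN 0.65 and E-cadherin, CDH1, 0.57 ± 0.06, from 68.6 ± 3.08 to 102 ± 4.48 FPKM. EPCAM, an epithelial adhesion molecule, rose by 0.45. Among those that fell were the gap junction protein GJA1 (-1.69, from 2.43 ± 0.121 to 0.0582 ± 0.0015 FPKM), the desmosomal genes PKP1 (-1.36) and DSG3 (-0.96), and NECTIN1 (listed as PVRL1, -0.97).

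**Figure D2:**
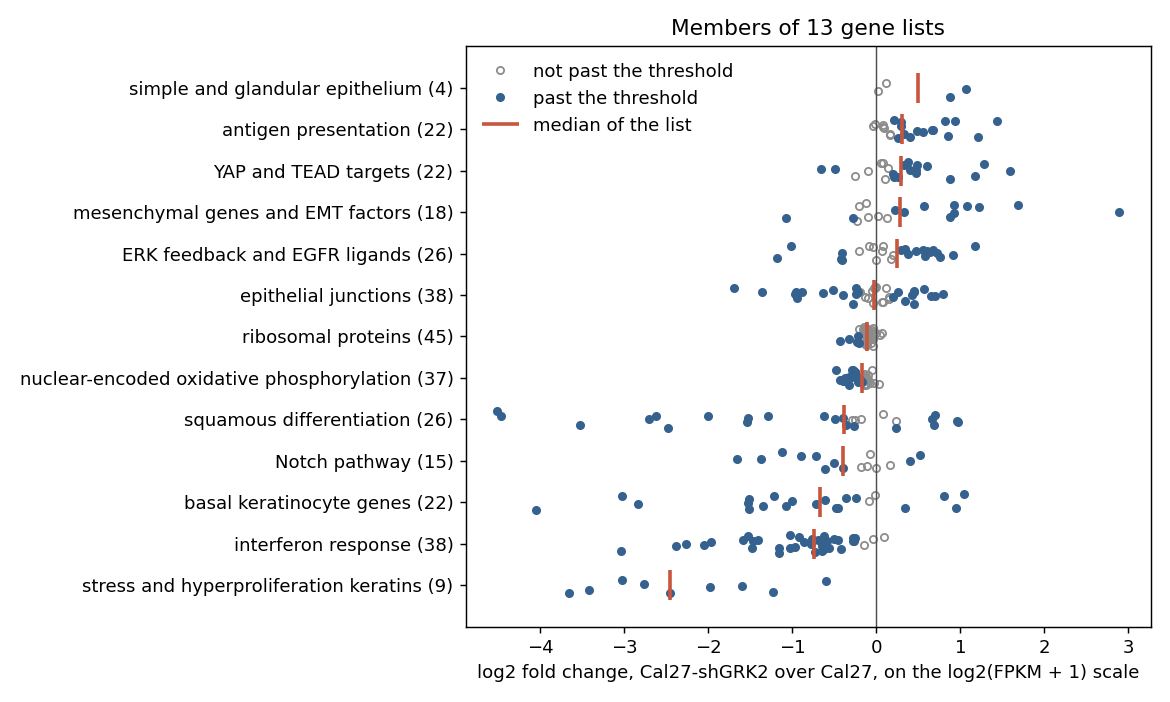
Log2 fold changes (Cal27-shGRK2 over Cal27, on the log2(FPKM + 1) scale) of the tested members of 13 gene lists, the 12 past the camera threshold and the epithelial junctions, with the number of members in brackets. Each circle is a gene, filled where it passed the threshold, and the bar is the median of the list. All 9 stress keratin genes lay below 0, while junction genes lay on both sides.

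Interferon-stimulated genes fell and antigen presentation genes rose. Of 38 interferon response genes, 35 fell, 0 rose and 3 did not pass, with a median of -0.74 (camera adjusted p = 1.9e-23, and adjusted p = 0.39 with an estimated correlation). IFI6 fell from 162 ± 8.25 to 18.9 ± 1.58 FPKM (log2 fold change -3.04), IFI27 from 385 ± 15.0 to 79.3 ± 2.77 FPKM (-2.26), OASL, an antiviral protein of the oligoadenylate synthetase family, by 2.38, and IFI44L by 2.05. Of 22 antigen presentation genes, 15 rose and 0 fell, with a median of 0.31 (camera adjusted p = 2.3e-08, and adjusted p = 0.39 with an estimated correlation). The class I gene HLA-B rose from 239 ± 13.4 to 554 ± 1.24 FPKM (1.21) and HLA-F by 0.85, and the class II genes HLA-DRB1 and HLA-DPA1 by 1.43 and 0.94. HLA genes are polymorphic and share reads with each other, so their single values are uncertain. Adjusted over the list alone, 35 interferon genes were lower and 16 antigen presentation genes were higher.

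The Notch, YAP and ERK lists passed, with members in both directions. Of 15 Notch pathway genes, 8 fell and 2 rose, with a median of -0.39 (camera adjusted p = 0.0028, and adjusted p = 0.56 with an estimated correlation). The ligands JAG2 (-1.66) and JAG1 (-1.37), the receptor NOTCH3 (-1.12) and the feedback gene NRARP (-0.90) fell, while the glycosyltransferase LFNG (0.53) and the receptor NOTCH2 (0.41) rose. Of 22 YAP and TEAD targets, 14 rose and 2 fell, with a median of 0.29 (adjusted p = 1.7e-04, and adjusted p = 0.54 with an estimated correlation). DLC1 (1.59), ANKRD1 (1.28), the ectonucleotidase NT5E (1.17) and the receptor kinase AXL (0.88) rose, and AMOTL1 (-0.66) and IGFBP3 (-0.49) fell. Of 26 ERK feedback genes and EGFR ligands, 13 rose and 5 fell, with a median of 0.25 (adjusted p = 0.010, and adjusted p = 0.70 with an estimated correlation). The ligand HBEGF (1.17), the AP-1 subunit FOSL1 (0.91), SPRY4 (0.75) and DUSP5 (0.72) rose, and the ERK phosphatase DUSP6 fell by 1.02. EGR1 had a log2 fold change of -1.18 (adjusted p = 0.035) and lost its call without Cal27 replicate 0 or 2 (adjusted p = 0.066 and 0.15) and without either Cal27-shGRK2 library (0.16 and 0.14), and with a mean of at least 5 FPKM (0.053). Adjusted over the list alone, the counts were 8 lower and 2 higher for Notch, 15 higher and 2 lower for YAP and TEAD, and 15 higher and 5 lower for ERK.

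Genes of oxidative phosphorylation were slightly lower. Of 37 nuclear-encoded members, 19 fell and 0 rose, with a median of -0.17 (camera adjusted p = 1.3e-07, and adjusted p = 0.54 with an estimated correlation), among them NDUFA4 (-0.48), COX7B (-0.43), COX6C (-0.40) and NDUFA1 (-0.39). Of 45 ribosomal protein genes, 5 fell and 40 did not pass, with a median of -0.11 (adjusted p = 1.0e-03, and adjusted p = 0.70 with an estimated correlation). RPS27 (-0.43) and RPS20 (-0.32) were the most changed. Under quantile normalization the median of the ribosomal list was 2.3e-04, with no shift (adjusted p = 0.76), and the calls of RPL30 (-0.23) and RPS23 (-0.21) were lost (adjusted p = 0.16 and 0.20). Without Cal27 replicate 2 both calls were also lost (0.092 and 0.070), as they were without the Cal27-shGRK2 library shared by replicates 0 and 1 (0.060 and 0.062), and that of RPL30 without replicate 2 of that group (0.083) and with limma without trend (0.056). Adjusted over the list alone, 20 oxidative phosphorylation and 5 ribosomal protein genes were lower.

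Among markers of other cell types, 2 of the 4 tested genes of simple and glandular epithelium rose, GATA3 (1.07), a luminal transcription factor, and KRT7 (0.88, from 45.5 ± 1.90 to 84.2 ± 3.15 FPKM), with the same count adjusted over the list alone. That list passed (camera adjusted p = 0.030, and adjusted p = 0.54 with an estimated correlation), but not under rescaling to a common total (adjusted p = 0.13) or with no filter (0.15). Of 3 tested neural and melanocyte markers, 2 were higher, the same number adjusted over the list alone, and the list did not pass (adjusted p = 0.13). Only 2 fibroblast markers and 2 blood or endothelial markers reached the filter, too few for the test. With no filter the blood and endothelial list was higher, just past the threshold (median 0.49, adjusted p = 0.0498), but not under rescaling to a common total (0.15), and the fibroblast list did not pass (0.67). Mitochondrial transcripts were not among the 18678 genes and were not analysed here.

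The 10 largest rises outside the lists above included HCLS1, an adaptor protein of blood cells (1.75 ± 0.0518 to 27.5 ± 1.24 FPKM, log2 fold change 3.37), the hair keratin KRT81 (3.23), C6orf15 (3.12), the cystatin CST6 (2.77), the BMP antagonist NOG (2.67) and the lipase MGLL (2.55). The trypsinogen gene PRSS2 (3.24) belongs to a family that shares reads, and it was listed at 0 in Cal27 replicates 0 and 2. Among the 10 largest falls were the imprinted RNA H19 (20.4 ± 0.812 to 0.738 ± 0.0252 FPKM, -3.62) and the collagenase MMP13 (-3.34). The rule also took 4 noncoding or unplaced features. AL031777.2 and the pseudogene AC009963.3 were listed at 0 in all 3 Cal27 libraries. Their FPKM in the Cal27-shGRK2 libraries were 19.2 and 5.97 for AL031777.2 and 3.56 and 6.69 for AC009963.3. The 5S_rRNA feature had FPKM of 7.43, 38.7 and 12.99 in Cal27 and was listed at 0 in both distinct Cal27-shGRK2 libraries, whereas the authors' mean for that group was 14.1. AC055736.3 had a log2 fold change of -5.28. The calls of AL031777.2 and AC055736.3 were lost without any Cal27 replicate 0, 1 or 2 (adjusted p = 0.11, 0.094 and 0.11 for the former, and 0.065, 0.053 and 0.068 for the latter). That of 5S_rRNA was lost without Cal27 replicate 0 or 2 (adjusted p = 0.069 and 0.15), without either Cal27-shGRK2 library (0.22 and 0.21), and with no filter beyond a value above 0 (0.060). With an additional Cal27-shGRK2 library computed from the authors' mean, an alternative chosen after seeing the data, the calls of 5S_rRNA, AC009963.3 and AL031777.2 were lost (adjusted p = 0.44, 0.22 and 0.23).

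The other fixed lists did not pass with the settings used above, though 5 of them did in some alternatives. Cell cycle genes did not shift, with 3 of 46 higher and 2 lower (camera adjusted p = 0.999, adjusted over the list alone 2 and 1), nor did cholesterol synthesis genes, with 1 of 25 higher and 2 lower (0.999, adjusted over the list alone 0 and 2). Epithelial regulators and polarity genes had 11 of 29 higher and 2 lower, with a median of 0.10 (adjusted p = 0.052, adjusted over the list alone 11 and 2). Epithelial regulators and polarity passed in 7 of 17 alternatives, among them all 3 scalings (adjusted p = 0.045, 0.034 and 0.044), and had an adjusted p of 0.70 with an estimated correlation. Carcinoma matrix and invasion genes had 20 of 44 higher and 11 lower, with a median of 0.18 but a mean of 0.02 (adjusted p = 0.096, adjusted over the list alone 22 and 14), and passed in 2 alternatives (lowest adjusted p = 0.028). Counts of members higher and lower were 4 and 8 of 30 for the unfolded protein and ATF4 response (adjusted p = 0.095), 7 and 12 of 28 for G protein-coupled receptors (0.13), 2 and 4 of 9 for cancer stem cell markers (0.13) and 2 and 6 of 16 for NRF2 targets (0.13). They were 8 and 10 of 28 for NF-kB and cytokine genes (0.32), 2 and 5 of 24 for p53 targets (0.52), 1 and 2 of 10 for histones (0.57) and 8 and 7 of 25 for TGF-beta and SMAD targets (0.65). They were 3 and 2 of 10 for receptor kinases, arrestins and RGS proteins (0.65), 3 and 4 of 11 for Wnt targets (0.80) and 10 and 6 of 30 for hypoxia and glycolysis (0.999), a list whose median (-0.06) and mean (0.01) differ in sign. Adjusted over the list alone, these 11 lists had counts of 5 and 10, 7 and 13, 2 and 5, 3 and 7, 9 and 12, 2 and 5, 1 and 2, 9 and 8, 3 and 2, 3 and 4, and 10 and 9, in the order given. The unfolded protein, G protein-coupled receptor and NRF2 lists each passed in 1 alternative (adjusted p = 0.029, 0.036 and 0.032).

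The authors' deposited table marks 2869 genes as significant, 1537 higher and 1315 lower with a finite fold change, and gives GRK2 a log2 fold change of -1.72. Of the 2252 of these genes that were tested here, 2168 also passed in limma, all in the same direction. A further 1789 genes passed in limma but are not marked significant in the authors' deposited table. Among them were SPRR1A, SOX2 and TAGLN, with q-values of 0.61, 0.15 and 0.065 in the authors' comparison. Their fold changes there were also negative (log2 -7.90, -6.25 and -2.48). AC055736.3, AL031777.2, RPL30, RPS20, RPS23 and 5S_rRNA (q = 0.85) are not marked significant there either. KRT13 and KRT14 are marked significant in that table (q = 6.1e-04 for each).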

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

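The authors' mean of Cal27-shGRK2, used above only in an added alternative, was looked at because its values do not follow from the deposited columns of that group. All tests in this part were chosen after the result was seen. The pattern is that 2 of the 3 Cal27-shGRK2 columns hold identical values. The authors' Cal27 value equalled the mean of the 3 Cal27 columns in 13362 of 13383 genes, but their Cal27-shGRK2 value matched the mean of its 3 columns in only 44 (0.329%), which argues against their comparison having used the repeated values. The values that an additional library would need (3 times the authors' mean minus the 2 distinct columns) were below 0 in 74 genes by at most 0.0002 FPKM, and in 0 genes by more than 0.1% of the authors' mean, and reached 1 FPKM in 13306 genes, with GRK2 at 18.0 FPKM. They differed from the 2 distinct columns by an SD of 0.237 and 0.251 on the log2 scale, against 0.288 for the widest pair of libraries within a group, which is consistent with an additional library having entered the authors' mean while its column holds a copy. No biological explanation was tested, and which replicate number was copied stays open.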

How the results depend on the processing

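The settings without a replicate and all planned settings were fixed before the data were examined. The 6 columns as deposited, the third library computed from the authors' mean and the second form of the replicate block were chosen after seeing the data. The log2 fold change of GRK2 stayed between -1.74 and -1.65 in all 16 alternatives, with adjusted p from 2.4e-78 to 7.4e-06. Of 100 genes taken by the rule or chosen later, 90 kept their direction and their side of the threshold in every alternative run, 10 lost their call in at least 1, and 0 reversed. Most of these genes were chosen for a large change or after their values were seen, so this does not extend to all genes called. Over all genes, 3368 of 3943, 3547 of 3939 and 3220 of 3939 calls were kept without Cal27 replicates 0, 1 and 2. Fewer were kept without either Cal27-shGRK2 library. Leaving out each of the 5 libraries in turn gave 2600 to 4028 genes past the threshold, 1218 to 2205 higher and 1088 to 1843 lower. Where this left 1 Cal27-shGRK2 library, it was assumed to vary like the other group. The lowest counts came without a Cal27-shGRK2 library. Counting the repeated values as 2 libraries gave 5386 genes and the computed additional library 4782, of which 3829 also passed with 5 libraries, all in the same direction. Genes with at least a 2-fold change numbered 533 with a pseudocount of 0.1, which shrinks low genes less, and 180 with a mean of at least 5 FPKM, where fewer genes were tested. An estimated correlation in camera left 0 of 12 lists past the threshold, the mesenchymal list included (median 0.28, adjusted p = 0.54, in a range of 6.2e-05 to 0.54 over its alternatives). That form of the test also has only 3 degrees of freedom, and the share of each in the lost calls was not separated. In the other alternatives 12 to 14 lists passed. The ribosomal protein list turned from -0.11 to 2.3e-04 under quantile normalization, where the cause was not tested beyond the weighing of scaling below. The direction of the epithelial junctions list turned with a mean of at least 5 FPKM (median -0.0046, adjusted p = 0.98), and its median was 0.02 when rescaled to a common total. It passed in none of its alternatives (adjusted p = 0.31 to 0.98), and the cause was not tested. The labels do not say whether the replicate numbers pair the samples, and the values could not decide it. Deviations of same-numbered libraries across genes correlated at 0.080 with the shared values as replicate 0, at -0.071 with them as replicate 1, and at 0.017 for replicate 2. With only 2 Cal27-shGRK2 libraries, the deviations of 1 mirror those of the other. With a replicate block, 3960 genes passed with the shared values as replicate 0 and 3481 with them as replicate 1. The calls of KRT6A, AC055736.3 and AL031777.2 were lost in both forms of the block, and those of SNAI2, RPL30, RPS23 and 5S_rRNA in the form with replicate 1. Depth is unknown, so how far it limits the low genes could not be set.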

Other observations

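The genes in the first 2 paragraphs, other than NOG, were chosen after their values were seen, and several belong to lists described above. The BMP target genes ID1 (54.3 ± 0.395 to 9.65 ± 0.435 FPKM, log2 fold change -2.38), ID3 (-1.74) and SMAD6 (-0.84) fell, as did the ligands BMP7 (-2.16) and BMP2 (-0.61), while NOG, which binds and blocks BMPs, rose by 2.67. ID2 rose by 0.66, the antagonist FST fell by 0.99, and BMP4 had a log2 fold change of 0.13 that did not pass (limma adjusted p = 0.28). No list of BMP genes alone was fixed, so these are single genes and not a tested group. ID1, ID2, ID3, SMAD6, BMP2 and BMP4 belong to the fixed list of TGF-beta and SMAD targets. That list did not shift, with 8 of 25 members higher and 7 lower (camera adjusted p = 0.65).

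Among receptors, the scavenging chemokine receptor ACKR3 (7.59 ± 0.572 to 0.259 ± 0.0066 FPKM, log2 fold change -2.77), the lysophosphatidic acid receptor LPAR3 (-1.41) and the thrombin receptor F2R (-0.76) fell, and the oxytocin receptor OXTR rose by 1.13. The squamous lineage factor TP63 fell from 31.8 ± 0.417 to 10.5 ± 0.0088 FPKM (-1.51) and the epithelial factor ELF3 by 0.82. These were the only 2 of 29 tested epithelial regulators and polarity genes called lower, whereas 11 were called higher. The parathyroid hormone-like gene PTHLH fell from 33.8 ± 1.31 to 2.49 ± 0.233 FPKM (-3.32). The calls of ACKR3, LPAR3, F2R, OXTR, TP63, ELF3 and PTHLH held in every alternative run. Each value is from 3 Cal27 and 2 Cal27-shGRK2 libraries.

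In the tests that follow, only that of scaling for the ribosomal protein list was chosen after its result was seen. Genes of the fixed lists that moved in 3 chromosomal clusters were 5 type I keratins of chromosome 17 that fell (median -3.03), 10 SPRR and S100A genes of chromosome 1 that fell (median -2.58) and 8 HLA genes of chromosome 6 that rose (median 0.83). These were taken by their direction. Of 3 other keratin or keratin-associated genes tested beside those of chromosome 17, 2 were called higher and 0 lower. Of 9 other S100A genes tested beside those of chromosome 1, 4 were called higher and 2 lower. Of 8 other HLA genes or pseudogenes of chromosome 6, 4 were called higher and 0 lower. A loss or gain of gene copies that reached beyond the 3 clusters would move their neighbours too. Tested genes within 1 Mb outside these families and lists had medians of -0.0734 (31 genes), -0.0348 (24 genes) and 0.00372 (108 genes). With all other genes within 1 Mb counted, family and list members included, the medians were -0.0722 (34 genes), -0.00804 (33 genes) and 0.0351 (120 genes). This argues against copy changes that span these neighbours as the cause, although the neighbours outside the families and lists that were called were all lower on chromosome 17 (8) and chromosome 1 (5). A copy change confined to the cluster genes would leave the neighbours unmoved, so these medians cannot decide it. Along all chromosomes, the medians of 235 windows of 10 Mb had an SD of 0.0534, above the highest of 1000 shuffles (0.0455) but by less than the factor of 1.5 set for copy changes, so copy changes elsewhere cannot be told apart from neighbouring genes regulated together; the windows with the lowest and highest medians were 70 to 80 Mb of chromosome 1 (-0.25, 25 genes) and 0 to 10 Mb of chromosome 7 (0.22, 75 genes). An effect of the knockdown, and any other difference between the 2 cell populations, stays open, since the labels do not say how many hairpins or clones Cal27-shGRK2 stands for.

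The slightly lower medians of the oxidative phosphorylation and ribosomal protein lists, neither of which passed with an estimated correlation (adjusted p = 0.54 and 0.70), and whose transcripts are short (median 930 and 783 bases against 2286 for all genes), were set against technical trends. Fold changes rose slightly with transcript length across genes (Spearman rho 0.13, genes not being independent replicates). After that trend was removed, the median of the oxidative phosphorylation list was -0.14 against -0.17 before. Under quantile normalization it stayed below the median of all genes (-0.13 relative to it). These values argue against either as the whole cause. Median-of-ratios scaling and rescaling to a common total (-0.16 relative to all genes in each) cannot decide. Each divides a library by a single factor, which shifts nearly all genes alike. The ribosomal protein median went from -0.11 to -0.0563 once the length trend was removed, so a part from transcript length cannot be told apart. Relative to all genes it lay at 0.00796 under quantile normalization, but at -0.10 under median-of-ratios scaling and -0.10 under rescaling to a common total, where the list still passed (adjusted p = 1.5e-04 and 0.0023). The criterion written for scaling, a median at or above 0 under at least 1 of the scalings, was thus met. It was met under quantile normalization, the only scaling of the 3 that does not shift nearly all genes alike. A rule set afterwards asks this of all 3, and since they differ a part from scaling stays open too.

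Of the 10 splits of the 5 libraries into 3 and 2, 1 gave as many genes, the real one with 3957, and the highest of the others gave 2. With 10 splits the share cannot fall under 0.05.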
